A study of Homo sapiens with 15 samples.

How the data were processed

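The data are 15 Affymetrix arrays of biotin-labelled cRNA made from total RNA of minor salivary glands, 1 array per gland. The deposited values are linear MAS5 signal intensities per probe set (54675 probe sets), per the submitters' processing notes for MAS5, with no version given. On every array the deposited signal had a mean of 100 after the lowest and highest 2% of probe sets were left out, so each array had been scaled before deposit. Rescaling to that trimmed mean moved no array by more than 0.00123%. Scanner images and detection calls were not used here.

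Probe sets were matched to genes with the platform's annotation table of 2016. Of the probe sets, 41097 carried exactly 1 gene symbol, 1801 several and 11777 none in that table, and only those with 1 symbol were used. Entrez gene IDs of 41043 probe sets were found in a RefSeq gene table for the human assembly GRCh38.p14, used for names and IDs only. Of the symbols as read for them, 0 differed from the names in that RefSeq table. Signals were converted to log2(signal + 16). Probe sets in the lowest 40% by mean over the 15 arrays were left out (signals below about 13.6), which kept 32805, and each gene was represented by its probe set with the highest mean, giving 14600 genes. Genes of the Y chromosome and XIST were left out of every table. Named genes had several probe sets in 55 of 130 gene and comparison pairs, and these pointed in different directions in 8.

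Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) on 14 arrays, with stage in 4 levels and batch in 2 as terms, 9 residual and 7.83 prior degrees of freedom. The control gland from an SS patient was not in the fit. The 5 contrasts were SS (mean of the 3 stage coefficients), early, moderate and advanced SS each minus non-SS control, and the mean of moderate and advanced minus early SS. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and 730 genes would have an unadjusted p under 0.05 by chance alone. All p-values are two-sided except those of Fisher's exact test on gene families, which is one-sided for more genes called than due, and ± values beside fold changes are standard errors.

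Gene lists, 34 in number, were written from textbook knowledge of gland, immune and other cell types. Each was tested with limma's camera with a preset correlation between genes of 0.01, again with the correlation estimated from the residuals, and with fry, which asks whether the genes of a list move on balance in 1 direction. Benjamini-Hochberg adjustment was over the 34 lists of a comparison. Members past the threshold were counted over all genes and adjusted over the list alone. A list score is the mean over its members of the log2 value minus the mean of the 4 controls. The contrasts, filters, lists and alternatives, and the rule for the genes named, were set before the data were examined. By that rule each comparison names the 10 largest rises and 10 largest falls past the threshold, or the 5 smallest p-values in a direction where fewer than 5 passed. It adds up to 4 members of each list by p, and always CHI3L1, CHI3L2, CHIT1, CHIA, TRIM21, RO60, SSB, CXCL13, TNFSF13B and AQP5, of which CHIA did not pass the filter on dim probe sets.

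The procedure was tested on simulated data with 50 genes changed at each of 4 sizes. For SS minus control, changes of log2 1, 2, 3 and 4 were recovered for 34%, 96%, 100% and 100% of genes, and 9 unchanged genes were called. For moderate SS minus control the shares for log2 1 and 2 were 22% and 86%, for advanced 6% and 56%, and for later minus early stages 46% and 98%. In the list test 20 of 20 simulated lists shifted by log2 1 and 0 of 20 unchanged lists were called for SS minus control. The simulated noise was independent between genes, whereas the real lists had a median estimated correlation of 0.295. The list test therefore does not tell how often lists of correlated genes are called by mistake.

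Alternatives were no batch term, a single batch, the control gland from an SS patient counted with the controls, 1 SS group (with batch, a contrast of the batch 2 glands), only the groups compared, quantile normalization or median centring, other pseudocounts (1 and 64), no filter or a 60% filter on dim probe sets, the mean of a gene's probe sets, no intensity trend, array weights, and leaving out each of 14 glands in turn. Chosen after the data were seen were the GAPDH 3'/5' ratio as a covariate, leaving out the 4 arrays with the highest ratio, and SS minus control with early and moderate SS weighted 2 to 1 as in batch 2. A change of sign counted as a reversal only where at least 1 of the 2 values was past the threshold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.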

Results

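Gene expression was measured on Affymetrix whole-genome arrays in 15 minor salivary glands, the small exocrine glands of the oral mucosa that are sampled in the diagnosis of Sjögren's syndrome (SS). SS is an autoimmune disease in which lymphocytes infiltrate salivary and lacrimal glands. The labels place 4 glands in a non-SS control group, 5 in early, 3 in moderate and 2 in advanced SS, and name 1 further gland as a control gland from an SS patient. How the stages were defined is not given in the sources used here. The labels also name 2 batches. All 4 non-SS controls belonged to batch 2 and both advanced glands to batch 1, as did the control gland from an SS patient. Batch 2 held early replicates 1 and 2 and moderate replicate 1, and batch 1 held the other 3 early and the other 2 moderate glands. Every array had the same trimmed mean signal of 100, and median signals lay between 17.9 and 27.7. Spearman correlations between arrays ranged from 0.779 to 0.93 over the 105 pairs.

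RNA quality differed with batch. The ratio of the 3' to the 5' GAPDH probe set, which rises as RNA is degraded or amplified from less material, averaged 6.27 ± 2.89 (SD, n = 8) in batch 1 and 3.06 ± 1.74 (SD, n = 7) in batch 2. The geometric means differed 2.02-fold (exact permutation test, two-sided, p = 0.0152). The main fit held batch as a term beside stage, and gene counts, leading genes and the main lists called are given below also without that term or, where a batch holds both groups, within a batch. Within batch 2 the SS glands are 2 early and 1 moderate, pooled by gland, with no advanced gland. The number of arrays limits the precision of all values, and p-values measure the spread between these glands. Fold changes are on the log2(signal + 16) scale, which understates changes of weakly expressed genes.

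The comparison of SS with non-SS glands asks which transcripts distinguish the diseased gland, with the 3 stages weighted equally. The B cell gene MS4A1 and the B cell chemokine CXCL13 rose most in SS glands. The fit held 10 SS and 4 control glands, but since all controls are in batch 2 the glands do not count alike in the difference. Moderate replicate 1 has a weight of 0.38, early replicates 1 and 2 0.31 each and the advanced glands 0.17 each, while the 5 early and moderate glands of batch 1 enter through the batch term with weights of -0.10 and -0.02. MS4A1 (gene ID 931), which encodes the B cell antigen CD20, rose by log2 4.79 ± 0.44 (SE; 27.7-fold) and exceeded every control in 10 of 10 SS glands. For MS4A1 the margin of early replicate 4 was slight (5.52 against 5.50 in control replicate 1, not adjusted for batch). CXCL13 (gene ID 10563), the chemokine that guides B cells into lymphoid follicles, rose by log2 4.75 ± 0.47 and exceeded every control in 9 of 10. GZMK, a granzyme of memory CD8 T cells (gene ID 3003), rose by log2 3.92 ± 0.39, also above every control in 9 of 10 glands. Their limma adjusted p-values were 6.78e-05, 8.13e-05 and 8.13e-05. Without the batch term the differences of MS4A1, CXCL13 and GZMK were smaller, at 3.78, 3.46 and 2.80, past the threshold. Within batch 2, where no advanced gland takes part, they were 3.32, 3.43 and 2.91, also past it, and the main fit with the same stage weights gives the same folds.

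Among the other named rises, the macrophage and dendritic cell chemokine CCL18 rose by log2 3.95 ± 0.49, the matrix metalloproteinase MMP9 (gene ID 4318) by 3.82 ± 0.54, the macrophage and dendritic cell metalloproteinase-like ADAMDEC1 by 3.63 ± 0.44, and CCL19, a ligand of CCR7, by 3.60 ± 0.56. The interferon-gamma-induced chemokine CXCL9 rose by log2 3.70 ± 0.74 (adjusted p = 0.00749; 0.154 without moderate replicate 1). HLA-DQA1, a class II antigen-presenting chain, stood at log2 3.71 ± 0.95 (adjusted p = 0.0369), but its 3 probe sets ranged from -1.87 to 3.71. The secretoglobin SCGB2A2 also passed at log2 3.94 ± 0.90, although its group means were 8.16 in controls and 9.28, 8.27 and 8.58 in early, moderate and advanced SS. Without the batch term its difference was 0.55 (adjusted p = 0.777). Within batch 2 all 10 named rises passed except HLA-DQA1 (2.24), with CCL18 at 2.34 and MMP9 at 2.36, and without the batch term these stood at 2.54 and 2.51. Of the 10 named rises, 7 passed whichever gland was left out, and the other 3 did not: CXCL9 as given, SCGB2A2 without moderate replicate 1 (4.72), early replicate 1 (3.31) or control replicate 3 (3.73), and HLA-DQA1 without 8 of the 14 glands.

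Of the 76 genes that fell, DLK1 (gene ID 8788), a Notch-related membrane protein, fell most, by 2.16 ± 0.35 (SE) on the log2 scale. The secretoglobin SCGB2A1 (gene ID 4246) fell by 2.11 ± 0.50, the nodal antagonist LEFTY1 by 1.95 ± 0.53, the Wnt pathway component DVL1 by 1.79 ± 0.40, and the sodium-dicarboxylate transporter SLC13A2 by 1.77 ± 0.35. Smaller falls were those of the creatine transporter SLC6A8 (-1.69 ± 0.45), MDGA1 (-1.66 ± 0.36), VSIG2 (-1.64 ± 0.44), the beta-catenin inhibitor CTNNBIP1 (-1.64 ± 0.34) and C1orf116 (-1.61 ± 0.30; 3 probe sets from -1.61 to -0.14). Their adjusted p-values ran from 0.00222 for DLK1 to 0.049 for LEFTY1. All 10 also passed without the batch term, with DLK1 at -1.45 and SCGB2A1 at -1.42, but within batch 2 only MDGA1 (-1.58) and CTNNBIP1 (-1.24) did, DLK1 standing at -1.46. None of these 10 falls passed without moderate replicate 1, where DLK1 stood at -1.83, SLC13A2 at -1.40 and SCGB2A1 at -1.54. LEFTY1, VSIG2, SLC6A8, SCGB2A1 and DVL1 also lost their calls without some other glands, for example DVL1 without early replicate 1 (-1.38) and SCGB2A1 without control replicate 1 (-1.97).

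The chitinase-like glycoprotein CHI3L1 (gene ID 1116) and the macrophage chitinase CHIT1 (gene ID 1118) rose by log2 2.83 ± 0.49 and 2.81 ± 0.53, with adjusted p = 0.00305 and 0.00524. Each exceeded every control in 4 of 10 SS glands. CHIT1 lay below every control in 2, both early, but with signals of 3.03 and 0.757 against a lowest control of 3.20. These lie far below the filter's signal of about 13.6, so that rank carries no weight. Without moderate replicate 1 they stood at 2.13 (adjusted p = 0.107) and 1.87 (0.165), within batch 2 at 1.66 (0.0851) and 1.52 (0.0939), and without a batch term at 1.15 (0.188) and 1.48 (0.0694). The remaining chitinase family members did not pass: 4 of 6 measured were not called, and CHI3L2 stood at -0.07 ± 0.41. TNFSF13B, the B cell survival factor BAFF, rose by log2 1.65 ± 0.41 (adjusted p = 0.0295) and exceeded every control in 8 of 10 SS glands, but stood at 1.12 (0.518) without moderate replicate 1. The call was also lost without advanced replicate 2 (1.44), early replicate 1 (1.73) or control replicates 1 (1.58), 2 (1.57) or 4 (1.55). AQP5, the apical water channel of acinar cells (gene ID 362), did not pass at -1.56 ± 0.70 (adjusted p = 0.259), whereas without the batch term it was -2.80 (0.0112) and 9 of 10 SS glands lay below every control. The autoantigen genes TRIM21 (0.26 ± 0.32), RO60 (-0.40 ± 0.36; its 4 probe sets ranged from -0.40 to 0.42) and SSB (0.80 ± 0.32; adjusted p = 0.205) did not pass, although SSB reached 1.15 (0.0411) without early replicate 2.

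Among the 34 gene lists, those of lymphocytes, antigen presentation and macrophages rose together. Of 18 measured T cell markers 12 rose and none fell, with 17 higher when adjusted over the list alone. TRBC1 stood at log2 2.94 ± 0.36, CD2 at 2.51 ± 0.33 and the interleukin 7 receptor IL7R at 2.51 ± 0.36. Of 17 B cell markers 11 rose, among them the transcription factor PAX5 (3.08 ± 0.47) and BANK1 (2.50 ± 0.38), and 17 were higher when adjusted over the list alone. Cytotoxic lymphocyte genes rose in 11 of 16 (15 over the list alone), with GZMA at 2.98 ± 0.34 and CCL5 at 2.81 ± 0.35. MHC class II genes rose in 11 of 12, all 12 over the list alone, with a median of log2 2.37. Macrophage markers rose in 12 of 17 (15 over the list alone), including the complement component C1QB (2.56 ± 0.35). Lymphoid chemokine and germinal centre genes rose in 7 of 13 (8 over the list alone), with CXCR4 at 3.42 ± 0.53 and LTB at 2.40 ± 0.42. All of these lists were called upward by limma's camera, and with an estimated correlation between genes their adjusted p-values lay between 0.02 for cytotoxic genes and 0.0351 for B cell markers. All 6 were called without the batch term too, with smaller medians from 0.95 for macrophage to 1.42 for T cell markers (1.90 and 2.09 in the main fit) and 1.12 for MHC class II genes. Within batch 2, among early and moderate glands only, all 6 were called with medians from 1.015 for lymphoid chemokine genes to 1.39 for T cell markers.

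Dendritic cell markers rose in 3 of 11 (CCR7 1.89 ± 0.34, CLEC10A 1.74 ± 0.33, CD83 1.37 ± 0.34), with 6 over the list alone and adjusted p = 0.0351 with an estimated correlation. Toll-like receptor genes rose in 6 of 16 (10 over the list alone), among them the RNA sensors TLR7 (2.18 ± 0.35) and TLR8 (2.19 ± 0.41), with adjusted p = 0.0414 with an estimated correlation. Complement genes rose in 5 of 15 (9 over the list alone; 0.0406 with an estimated correlation). Interferon-gamma-induced genes rose in 5 of 13 (11 over the list alone), including GBP1 (2.19 ± 0.44) and the class II transactivator CIITA (1.75 ± 0.38), with adjusted p = 0.0528 with an estimated correlation. Type I interferon-stimulated genes were called upward as a list (median log2 0.40), and SAMD9L (1.59 ± 0.43) alone of 26 members rose, or 2 over the list alone, with adjusted p = 0.563 with an estimated correlation. That list's call was lost without moderate replicate 1 (median 0.19). Its scores, which involve no batch term, averaged 0.91 ± 0.97 (SD) in early, 0.74 ± 0.44 in moderate and 0.92 ± 0.35 in advanced SS above the control mean. Proliferation genes rose in 3 of 16 (8 over the list alone), namely TYMS, BUB1B and TOP2A, with adjusted p = 0.0939 with an estimated correlation.

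MHC class I genes rose in 4 of 15 (NLRC5 2.20 ± 0.34, TAP2 1.73 ± 0.31, PSMB9 2.16 ± 0.44, HLA-F 1.82 ± 0.44; 7 over the list alone), with adjusted p = 0.171 with an estimated correlation. Plasma cell markers rose in 4 of 14 (5 over the list alone), PRDM1 standing at 1.95 ± 0.41, with adjusted p = 0.209 with an estimated correlation. One immunoglobulin gene of 7, IGHM, rose (2.06 ± 0.55; 3 over the list alone), with adjusted p = 0.405 with an estimated correlation, and the list's call was lost without control replicate 3 (0.62) or early replicate 2 (0.45). Metalloproteinases and their inhibitors rose in 3 of 15 (ADAMDEC1, MMP9 and MMP12; 3 over the list alone), with adjusted p = 0.203 with an estimated correlation. Endothelial markers were called upward with only VCAM1 (1.97 ± 0.44) rising of 15, and fibroblast and matrix genes with 0 of 18, each with adjusted p = 0.513 with an estimated correlation. Their medians of 0.47 and 0.53 were -0.31 and -0.22 without a batch term. The endothelial call was also lost without advanced replicate 2 (0.31) or early replicate 1 (0.31), and the fibroblast call without early replicate 1 (0.33). Skeletal muscle markers, not a tissue of the gland itself, were called upward with 0 of 14 members passing (median 1.09), with adjusted p = 0.513 with an estimated correlation. Without early replicate 2, whose score for these markers was 2.99 above the control mean, the median was -0.01.

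Lists of ductal, acinar, myoepithelial and nerve cells were called lower with few single genes passing, and none kept its call with an estimated correlation. Ductal markers were called lower (median -0.85), with 1 of 19 lower, the epithelial sodium channel subunit SCNN1A (-1.20 ± 0.30), also 1 over the list alone. Their adjusted p was 0.228 with an estimated correlation, and without moderate replicate 1 the median was -0.32 and the call was lost. Acinar transport and secretion genes were called lower (median -0.41) with 0 of 23 passing and 1 over the list alone, the muscarinic receptor CHRM3 (-1.08 ± 0.29; adjusted p = 0.0503). With an estimated correlation the list's adjusted p was 0.209. Myoepithelial and smooth muscle markers were called lower with 0 of 12 passing (median -0.63), with adjusted p = 0.513 with an estimated correlation. The call was lost without control replicate 1 (-0.47) or 3 (-0.56) and turned to 0.14 without moderate replicate 1. Nerve and Schwann cell markers were called lower with 1 of 7 lower, the receptor ERBB3 (-1.24 ± 0.24; also 1 over the list alone), with adjusted p = 0.209 with an estimated correlation. This call was lost without control replicate 1, early replicate 2 or moderate replicate 1 (median -0.38 in each).

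The other lists were not called. Salivary secretory proteins had 0 of 24 members passing (median -0.20, mean 0.09), and without moderate replicate 1 the list was called upward at 0.11. No member passed among Sjögren autoantigens (6), adipocyte (11), oral squamous epithelium (6), red blood cell (4), neutrophil (10) or mast cell markers (8), endoplasmic reticulum stress genes (16) or oxidative phosphorylation genes (19). Over the list alone, 3 neutrophil markers were higher and 1 lower, and 1 autoantigen gene, CHRM3, was lower. Of 14 immediate early genes, which respond to tissue handling, only EGR3 rose (1.36 ± 0.30), with 1 higher and 2 lower over the list alone. The chitinase family as a list was not called (2 of 6 higher, 2 over the list alone), with a mean of 0.82 and a median of -0.10. Neutrophil and chitinase lists became called without early replicate 1, at medians of 0.40 and 0.03.

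In all, 562 of 14600 genes were called between SS and control (486 higher, 76 lower), and 2493 had an unadjusted p under 0.05. Without a batch term the count was 1672 (362 shared) and the balance of directions turned, with 792 higher and 880 lower. With the control gland from an SS patient among the controls it was 1082 (739 higher, 343 lower). Contrasts without the advanced stage called fewer. Within batch 2, for 2 early and 1 moderate gland, the count was 224 (206 higher, 18 lower; 201 shared). The main fit with the stages weighted in the same way, a setting chosen after the data were seen, gave 20, all higher. Taking SS as 1 group beside batch gave 0 (1034 at unadjusted p under 0.05), and since all controls are in batch 2 that contrast also rests on the 3 SS glands of batch 2. All named genes had the same fold in these 3 settings, so the counts differ by the spread and degrees of freedom of each fit. Of the 34 lists 23 were called, against 16 without a batch term and 19 within batch 2. Leaving out moderate replicate 1, the only moderate gland of batch 2, left 60 genes, all higher, 56 of them among the 562.

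**Figure D1:**
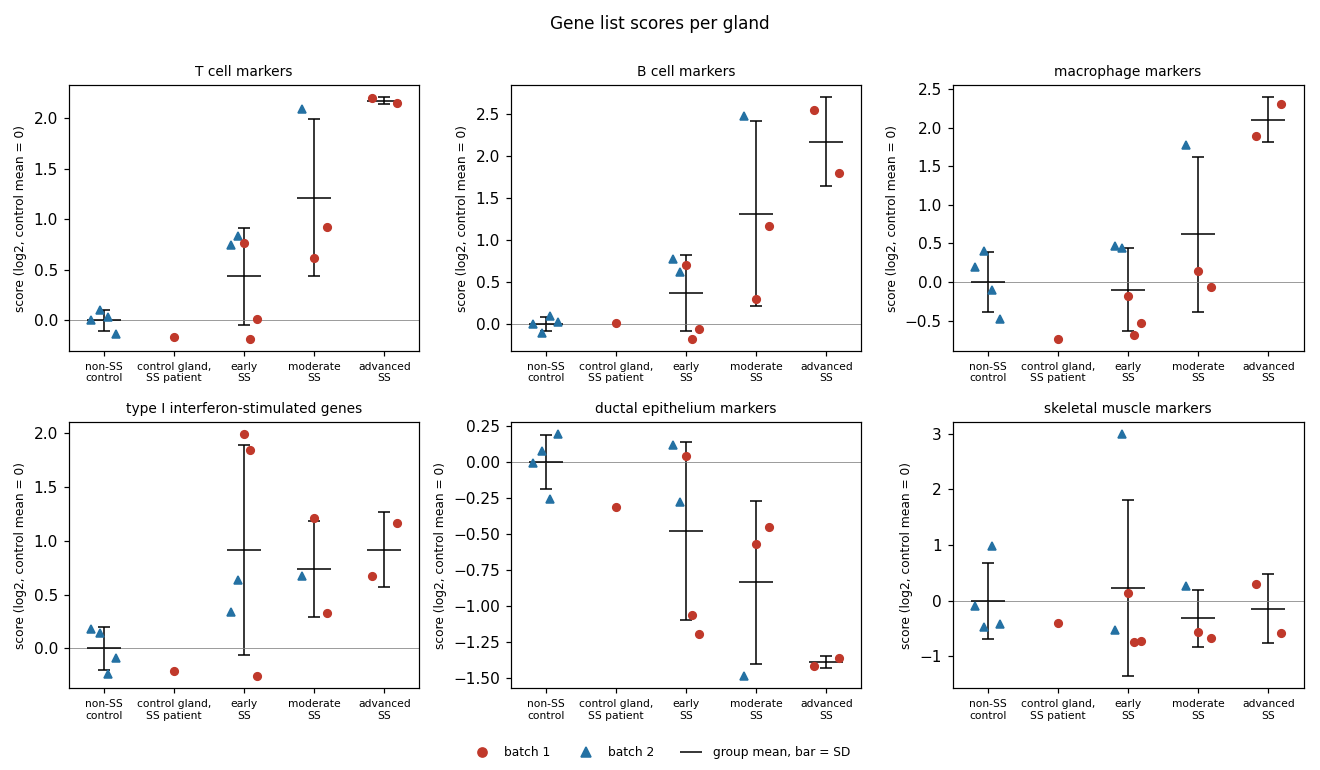
Score of 6 gene lists in each of the 15 glands (mean over the list of the log2 value minus the control mean) by group, with circles for batch 1, triangles for batch 2, and the group mean with SD as bars. T cell scores averaged 0.43 ± 0.48 in early, 1.21 ± 0.78 in moderate and 2.18 ± 0.03 in advanced SS, and 1 early gland stood apart at 2.99 for skeletal muscle markers.

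Early SS compared with control asks what is already altered at the first stage (5 against 4 glands, early replicates 1 and 2 of batch 2 weighing 0.39 each and the other 3 0.07 each). Lymphocyte genes had the smallest p-values, but none passed the threshold. GZMK stood at log2 2.52 ± 0.38 (adjusted p = 0.0707), CXCL13 at 2.63 ± 0.46 (0.156), MS4A1 at 2.36 ± 0.43 (0.156), the T cell chemokine CCL5 at 1.86 ± 0.34 (0.156) and GZMA at 1.68 ± 0.33 (0.282). MS4A1 exceeded every control in 5 of 5 early glands, and CXCL13 and GZMK did in 4 of 5. For MS4A1 the margin of early replicate 4 was slight (5.52 against 5.50 in control replicate 1, not adjusted for batch). Without the batch term GZMK stood at 1.64, CXCL13 at 1.60, MS4A1 at 1.55, CCL5 at 1.12 and GZMA at 1.09. The lower values with the smallest p were those of MDGA1 (-1.56 ± 0.35), CMIP (-1.38 ± 0.32; 3 probe sets from -1.38 to -0.29), TFAP4 (-1.36 ± 0.32), BMP15 (-1.15 ± 0.29) and ATP6AP1-DT (-1.03 ± 0.28), with adjusted p between 0.375 and 0.546. CHI3L1 (1.48 ± 0.48), CHIT1 (1.10 ± 0.52), TNFSF13B (0.94 ± 0.40), SSB (0.63 ± 0.31), RO60 (-0.47 ± 0.35) and AQP5 (-0.83 ± 0.69) did not pass either. Without the batch term CHI3L1 stood at 0.14, CHIT1 at 0.04 and SSB at 0.14, whereas TNFSF13B stood at 1.07 and AQP5 at -1.81. In batch 2, early replicates 1 and 2 had CHI3L1 values of 6.95 and 7.73 (control mean 6.255) and CHIT1 values of 4.32 and 5.86 (4.52). The early glands of batch 1 were lower, from 5.48 to 6.30 for CHI3L1 and from 4.07 to 4.30 for CHIT1. The size of these 2 differences thus depends on how batch is treated.

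Of the lists in early SS, 19 were called, 17 upward and 2 downward, but 0 were called with an estimated correlation and 1, cytotoxic lymphocyte genes, by fry. For cytotoxic genes 12 of 16 members were higher over the list alone (median log2 0.95; adjusted p = 0.0516 with an estimated correlation). T cell markers were higher in 11 of 18 over the list alone (median 1.05; adjusted p = 0.0958 with an estimated correlation), with CD6 at 1.70 ± 0.38 and TRBC1 at 1.53 ± 0.35. Interferon-gamma-induced genes were higher in 6 of 13 over the list alone (adjusted p = 0.162 with an estimated correlation), among them CXCL10 (2.88 ± 0.68) and GBP1 (1.79 ± 0.44). B cell markers were higher in 3 of 17 over the list alone (median 0.85; adjusted p = 0.17 with an estimated correlation). Ductal markers, called downward at a median of -0.47 (adjusted p = 0.435 with an estimated correlation), stood at -0.05 within batch 2. When the batch term was left out 9 lists were called. Cytotoxic (0.64), T cell (0.54) and B cell lists (0.32) were among them, while macrophage (-0.17) and MHC class II genes (-0.14) were not.

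limma called 0 of 14600 genes between early SS and control, and 1032 had an unadjusted p under 0.05. Simulated changes of log2 2 were recovered for 90% of genes in this comparison, and those of log2 1 for 30%. In that simulation 169 genes were called, and the adjusted threshold is stricter where few genes change. GZMK, CXCL13 and MS4A1 stood above log2 2 in the data and did not pass, so changes of that size can have been missed. Other settings called 0 to 4 genes, named here after their values were seen: CXCL13 and SMR3A within batch 2, and CCL5, CXCL13, GZMK and MS4A1 with array weights. Leaving out a single gland gave GZMK and CCL5 (early replicate 3), GZMK (early replicate 4), LPO and ZNF595 (early replicate 2), or SMR3A (moderate replicate 1). The early difference within batch 2 and that without moderate replicate 1 are the same contrast, early replicates 1 and 2 against the controls. SMR3A stood at log2 4.80 in both.

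Moderate SS compared with control repeats the question at the next stage (3 against 4 glands, moderate replicate 1 weighing 0.57 and the others 0.21 each). MS4A1 and CXCL13 had the largest rises, MS4A1 rising by log2 5.26 ± 0.49, CXCL13 by 5.04 ± 0.52, the Fc receptor-like FCRL3 by 3.83 ± 0.45 and the lymphocyte surface antigen CD52 by 3.81 ± 0.57. GZMK rose by 3.69 ± 0.43, CXCL9 by 3.56 ± 0.82, CCL18 by 3.52 ± 0.55, CXCR4 by 3.48 ± 0.59, CCL19 by 3.44 ± 0.62 and MMP9 by 3.41 ± 0.59. In limma, adjusted p ran from 7.67e-05 for MS4A1 to 0.0346 for CXCL9. The named falls were DLK1 (-2.15 ± 0.39), DVL1 (-1.82 ± 0.44), the Schwann cell protein PRX (-1.77 ± 0.36), SLC13A2 (-1.68 ± 0.38), FOXO6 (-1.66 ± 0.39), MDGA1 (-1.63 ± 0.40), ZNF584 (-1.59 ± 0.34), TMEM63A (-1.45 ± 0.35; 4 probe sets from -1.45 to -0.32), the mucin MUC15 (-1.40 ± 0.33) and the lysosomal protease CTSF (-1.30 ± 0.31). Only MS4A1 and CXCL13 of the 10 named rises and 0 of the 10 named falls passed whichever gland was left out. Without moderate replicate 1 FCRL3 stood at 2.73, GZMK at 3.22 and DLK1 at -1.66, and MUC15 lost its call without 11 of the 14 glands, DVL1 and MDGA1 without 10, TMEM63A without 9 and CXCL9 without 5. Without the batch term MS4A1 was 4.37 and CXCL13 3.89, while CCL18 (2.27), CCL19 (2.41), MMP9 (2.26) and 7 of the falls did not pass. CHIT1 (2.35 ± 0.58, adjusted p = 0.052) and CHI3L1 (2.02 ± 0.54, 0.0747) did not pass. Within batch 2, where moderate replicate 1 is the only moderate gland, they stood at 3.41 and 2.81, values of that gland against the controls, and without it at 0.93 and 0.97. TNFSF13B (1.30 ± 0.45), TRIM21 (0.04 ± 0.36), RO60 (-0.29 ± 0.40) and AQP5 (-1.45 ± 0.77) did not pass.

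In moderate SS 15 lists were called upward and 4 downward, and 6 kept their call with an estimated correlation. Those 6 were T cell (10 of 18 higher, 17 over the list alone), cytotoxic (7 of 16, 13 over the list alone), B cell (5 of 17, 15 over the list alone), MHC class II (6 of 12, 12 over the list alone), macrophage (7 of 17, 12 over the list alone) and lymphoid chemokine lists (6 of 13, 7 over the list alone). Their adjusted p-values with an estimated correlation lay between 0.0185 and 0.0482. A fit with no batch term called 16 lists, these 6 among them, with macrophage markers at a median of 0.54 (main 1.68) and MHC class II genes at 1.06 (2.22). Examples were TRBC1 (2.90 ± 0.40), PAX5 (3.29 ± 0.52), HLA-DQB1 (2.81 ± 0.47) and MS4A4A (2.85 ± 0.38). Interferon-gamma-induced genes were higher in 2 of 13 (6 over the list alone), CIITA and CXCL9, with adjusted p = 0.0761 with an estimated correlation. Ductal markers were called lower with 0 of 19 passing (median -0.82; adjusted p = 0.279 with an estimated correlation), and the median was 0.01 without moderate replicate 1.

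In total 243 genes were called in moderate SS (228 higher, 15 lower; 1861 at unadjusted p under 0.05), against 148 without a batch term (96 higher, 52 lower; 71 shared), so falls were a larger part there. Within batch 2 the moderate arm is a single gland whose spread is taken from the other groups, and the 921 genes called (603 higher, 318 lower; 230 shared) describe that gland. Without moderate replicate 1 the count was 3, CXCL13, MS4A1 and OPRPN, named after their values were seen. It was 383 without early replicate 3, and 153, 146 and 99 without control replicates 2, 3 and 4.

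Advanced SS compared with control covers the last stage named in the labels (2 against 4 glands, with no batch in common). MS4A1 had the largest rise, by 6.76 ± 0.61, CCL18 by 6.59 ± 0.68, CXCL13 by 6.59 ± 0.66, MMP9 by 6.20 ± 0.74, ADAMDEC1 by 6.18 ± 0.61, the macrophage apolipoprotein APOC1 (gene ID 341) by 6.17 ± 0.64, HLA-DQB1 by 5.94 ± 0.59 (6 probe sets from 0.39 to 6.74) and the leukocyte integrin ITGB2 by 5.62 ± 0.57. HLA-DQA1 stood at 5.76 ± 1.32 (3 probe sets from -0.82 to 5.76) and TMEM255A rose by 5.57 ± 0.93. CHI3L1 rose by 5.00 ± 0.68 and CHIT1 by 5.00 ± 0.73, with adjusted p = 2.35e-04 and 4.21e-04, and both exceeded every control in 2 of 2 glands. TNFSF13B rose by 2.70 ± 0.57 (adjusted p = 0.00634; 2.08 and 0.0867 without advanced replicate 2). Differences without the batch term were smaller: 5.42 for MS4A1, 4.87 for CXCL13, 2.77 for CHI3L1 (adjusted p = 0.0412), 3.23 for CHIT1 and 3.06 for ITGB2, each still past the threshold.

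Of the 344 genes that fell in advanced SS, SCGB2A1 fell most, by 3.71 ± 0.70, the microseminoprotein MSMB by 3.42 ± 0.91, WFDC1 by 3.38 ± 0.70, the airway and salivary defence protein BPIFB1 by 3.26 ± 0.96, the secretory cell transcription factor SPDEF by 3.21 ± 0.81 (5 probe sets from -3.21 to 0.06), DLK1 by 3.20 ± 0.49, the neuropeptide precursor TAC1 by 3.16 ± 0.83 and the calpain CAPN9 by 3.01 ± 0.84. LINC00960 (-3.42 ± 0.97; 3 probe sets from -3.42 to -0.47) and C19orf33 (-3.31 ± 0.95) completed the named falls, and these last did not pass without the batch term (-1.50 and -2.15). Only SCGB2A1 and DLK1 of these 10 passed whichever gland was left out, and 9 of the 10 named rises did, HLA-DQA1 being the exception. AQP5 did not pass at -2.40 ± 0.97 (adjusted p = 0.16), but reached -3.10 (0.0469) without early replicate 2 and -4.03 (0.00897) without the batch term, its group means being 10.99 ± 0.86 (SD, n = 4) in controls and 6.96 ± 1.44 (n = 2) in advanced SS. SSB (1.11 ± 0.44), TRIM21 (0.72 ± 0.45) and RO60 (-0.43 ± 0.50) did not pass.

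In advanced SS 18 lists were called upward and 5 downward, and 9 kept their call with an estimated correlation, all upward. Macrophage markers rose in 16 of 17 (median log2 3.38; 16 over the list alone), T cell markers in 17 of 18 (3.28; 17), B cell markers in 15 of 17 (2.80; 17), cytotoxic genes in 13 of 16 (2.63; 16) and MHC class II genes in 11 of 12 (4.13; 12). Dendritic cell, lymphoid chemokine, Toll-like receptor and complement lists also kept their calls, with adjusted p between 0.0231 and 0.0307 with an estimated correlation. With no batch term 20 lists were called, these 9 among them, with medians such as 2.19 for macrophage and 2.35 for T cell markers. Interferon-gamma-induced genes rose in 9 of 13 (12 over the list alone; adjusted p = 0.0684 with an estimated correlation), while 0 of 26 type I interferon-stimulated genes passed and that list was not called (median 0.41). It was called upward without the batch term (0.84), with the control gland from an SS patient among the controls (0.61), and without advanced replicate 1 (0.42) or early replicates 1 (0.53), 3 (0.62) or 4 (0.66). Acinar transport genes fell in 3 of 23, CHRM3 (-1.96 ± 0.41), the sodium pump subunit ATP1B1 (-1.15 ± 0.29) and the aquaporin AQP3 (-1.76 ± 0.51), with 5 lower over the list alone and adjusted p = 0.19 with an estimated correlation. Ductal markers fell in 2 of 19, SCNN1A (-2.23 ± 0.42) and the keratin KRT18 (-1.95 ± 0.55), with 6 over the list alone and adjusted p = 0.222 with an estimated correlation.

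Altogether 1131 genes were called in advanced SS (787 higher, 344 lower; 3052 at unadjusted p under 0.05), against 1356 without a batch term (670 shared). No batch holds both groups, so a within-batch value cannot be had and the adjusted folds rest on a batch term estimated from early and moderate glands. The count was 542 without moderate replicate 1, 515 without advanced replicate 2 and 719 with the GAPDH 3'/5' ratio as a covariate, which was chosen after the data were seen.

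**Figure D2:**
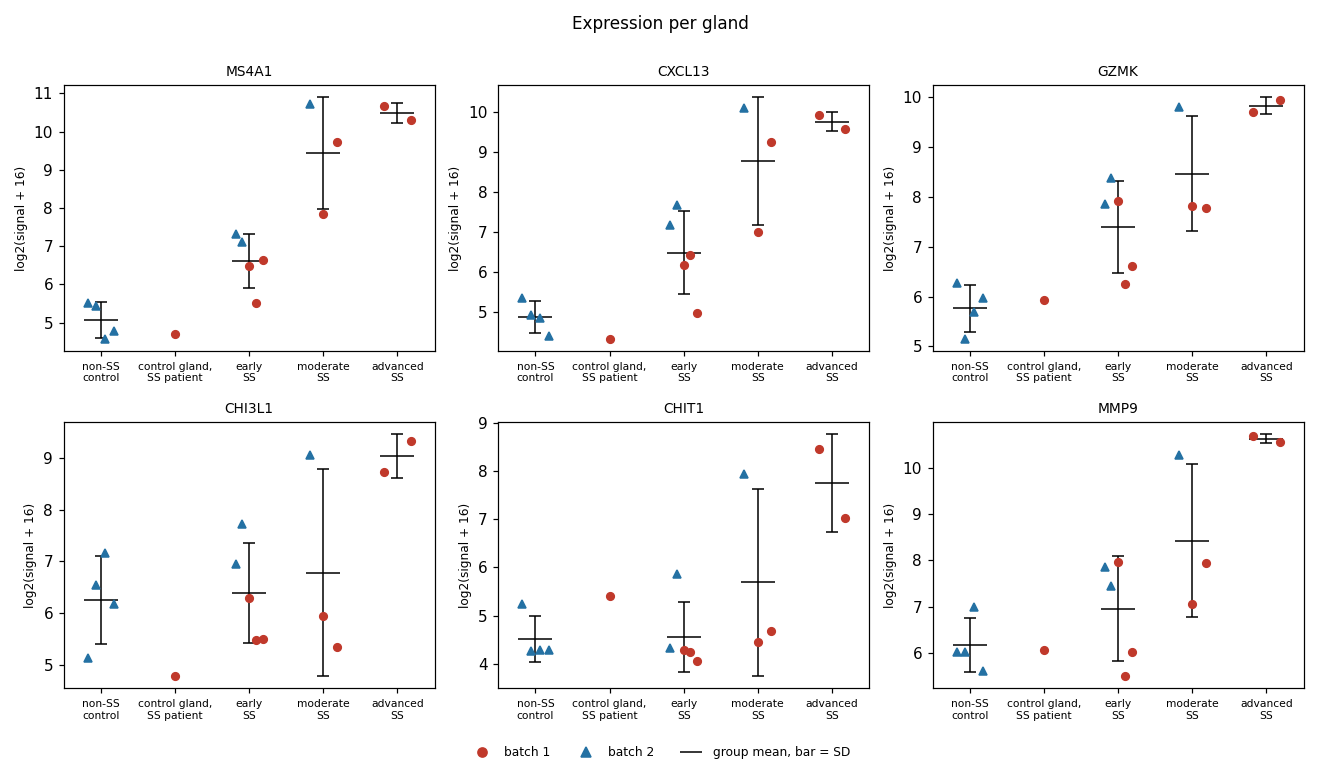
Log2(signal + 16) of 6 named genes in each of the 15 glands by group, with circles for batch 1, triangles for batch 2, and the group mean with SD as bars. MS4A1 averaged 5.07 in controls, 6.62 in early, 9.43 in moderate and 10.49 in advanced SS, whereas CHIT1 stood at 4.52, 4.56, 5.69 and 7.75.

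The comparison of moderate and advanced SS with early SS asks which transcripts differ with stage among SS glands and does not use the control glands in its contrast (5 against 5 glands). Macrophage, B cell and class II transcripts rose from early to later stages. APOC1 rose by log2 3.95 ± 0.37, MS4A1 by 3.66 ± 0.35, ADAMDEC1 by 3.45 ± 0.36, HLA-DQB1 by 3.31 ± 0.34 (6 probe sets from 1.22 to 3.31), CCL18 by 3.30 ± 0.40, CXCL13 by 3.19 ± 0.38, MMP9 by 2.98 ± 0.43, FCRL3 by 2.94 ± 0.33 and CD52 by 2.86 ± 0.42. HLA-DQA1 stood at 3.53 ± 0.77 (adjusted p = 0.0122; 0.128 without moderate replicate 1 and 0.0578 without advanced replicate 2). The other 9 named rises passed whichever gland was left out. Within batch 1, APOC1 (3.58), MS4A1 (3.42), ADAMDEC1 (2.88) and CXCL13 (3.09) also passed, with adjusted p between 0.00583 and 0.0248.

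The named falls with stage were CNMD (-1.88 ± 0.38), LRRC31 (-1.80 ± 0.37), the amino acid transporter SLC6A14 (-1.68 ± 0.25), the Wnt inhibitor WIF1 (-1.63 ± 0.45), xanthine dehydrogenase XDH (-1.62 ± 0.31; 2 probe sets from -1.62 to -0.23), WFDC1 (-1.61 ± 0.41), LINGO1 (-1.60 ± 0.35), the lipase LIPH (-1.59 ± 0.41), DLK1 (-1.55 ± 0.29) and C9orf152 (-1.47 ± 0.26). SLC6A14, XDH, DLK1 and C9orf152 passed whichever gland was left out, but none of the 10 passed without the batch term (SLC6A14 -1.34) and only SLC6A14 did within batch 1 (-1.74). Without moderate replicate 1, WIF1, WFDC1 and LIPH stood at -1.48, -0.98 and -1.09 and did not pass, and WIF1 lost its call without 10 of the 14 glands. CHIT1 rose by 2.57 ± 0.43 (adjusted p = 0.00195; 1.95 within batch 1, 0.0428) and CHI3L1 by 2.04 ± 0.39 (0.00568), the latter standing at 1.58 within batch 1 (0.067) and at 1.58 without moderate replicate 1 (0.0684). Without moderate replicate 1 batch 2 holds no later gland, so both CHI3L1 settings compare the same batch 1 glands and are not separate checks. TNFSF13B (1.06 ± 0.33, adjusted p = 0.0796), TRIM21 (0.38 ± 0.26), SSB (0.26 ± 0.26), RO60 (0.11 ± 0.29), CHI3L2 (-0.52 ± 0.33) and AQP5 (-1.09 ± 0.57) did not pass.

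With stage, 16 lists were called upward and 6 downward, and 9 upward and 1 downward kept their call with an estimated correlation. Macrophage markers rose in 13 of 17 (median log2 1.85; 16 over the list alone), with C1QB at 2.65 ± 0.29 and C1QC at 2.60 ± 0.29. T cell markers rose in 13 of 18 (1.58; 16 over the list alone), B cell markers in 11 of 17 (1.49; 16 over the list alone) and MHC class II genes in 11 of 12 (2.37; 12 over the list alone). Cytotoxic (10 of 16), dendritic (5 of 11), lymphoid chemokine (7 of 13), Toll-like receptor (7 of 16) and complement genes (6 of 15) rose as well, and all 9 lists had adjusted p between 0.018 and 0.0362 with an estimated correlation. All 9 were called also without the batch term and within batch 1, where macrophage markers stood at 1.70 and 1.66 and T cell markers at 1.39 and 1.41. Nerve and Schwann cell markers fell as a list, with 1 of 7 lower, ERBB3 (-1.01 ± 0.20), 5 lower over the list alone, and adjusted p = 0.0434 with an estimated correlation. Myoepithelial and smooth muscle markers were called lower with 2 of 12 falling, MYH11 (-1.08 ± 0.27) and MYLK (-0.77 ± 0.20), and 6 over the list alone, with adjusted p = 0.201 with an estimated correlation. Type I interferon-stimulated genes had 0 of 26 passing (median -0.20), and the list was called lower without early replicate 5 (-0.62), advanced replicate 2 (-0.36) or moderate replicate 1 (-0.39).

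Between later and early SS 714 genes were called (546 higher, 168 lower; 2468 at unadjusted p under 0.05). The count was 191 without a batch term (all 191 shared) and 63 within batch 1 (all 63 shared). It was 203 without moderate replicate 1 (193 shared), 363 without advanced replicate 2, 427 without advanced replicate 1 and 446 without early replicate 4.

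**Figure D3:**
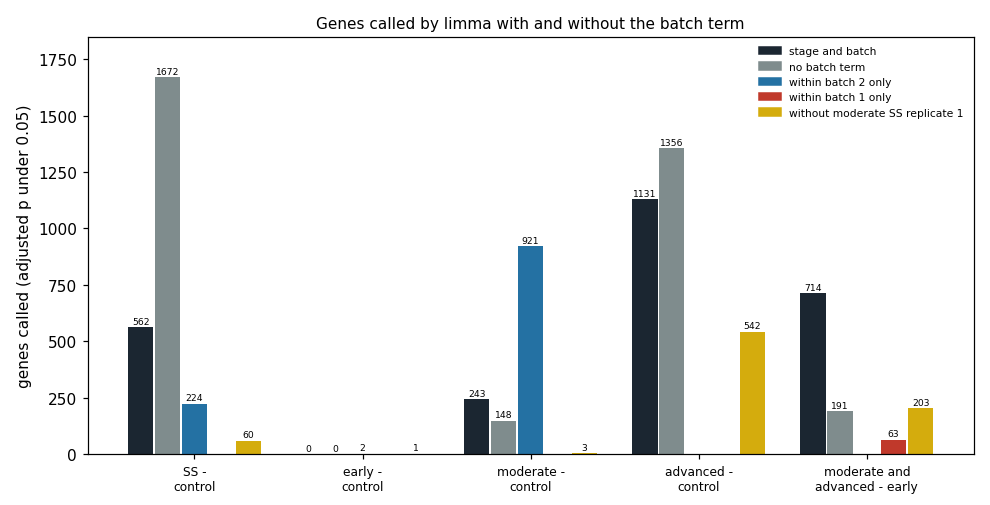
Number of genes called by limma (adjusted p under 0.05) in each of the 5 comparisons, with bars for stage and batch, no batch term, batch 2 only (without advanced glands), batch 1 only and all but moderate replicate 1. The SS count changed from 562 to 1672 without a batch term and to 60 without that gland.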

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

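All patterns and tests here were chosen after the main results were seen, and where a bound is called written first, it preceded only that test's own value. At the same stage the leukocyte score (80 genes) was lower in batch 1 than in batch 2, with a batch coefficient of -0.9996 ± 0.22 (SE). It was -0.99 ± 0.34 with the GAPDH 3'/5' ratio as a covariate (bound written first), so adjusting for that ratio did not account for it. Arrays had been scaled, so a median over all genes near 0 decides nothing. The leukocyte score minus each array's median over all genes still had a batch coefficient of -0.88 ± 0.20 (bound written after). The lower score was thus not shared by genes at large. Scaling would have removed a common factor beforehand, so this value does not test for one. Without moderate replicate 1 the batch coefficient of the leukocyte score was -0.71 ± 0.23 (bound written first). That gland's leukocyte content may account for part of the batch difference, and the question stays open. Whether glands of a stage differed in infiltration between the batches was not tested otherwise.

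Ductal markers were lower in SS glands, by a score of -0.85 ± 0.41. Dilution of glandular RNA by leukocytes would lower other gland compartments alike. The ductal score minus the mean of 6 other non-leukocyte scores was -0.79 ± 0.29 (bound written after related values were seen), and -0.52 ± 0.22 without a batch term. Both are beyond 2 SE as the bound asks, but -0.50 ± 0.33 without moderate replicate 1 is not. The 6 scores went both ways. Acinar (-0.56 ± 0.22), myoepithelial (-0.44 ± 0.31) and nerve scores (-0.44 ± 0.19) were lower. Fibroblast (0.60 ± 0.53), endothelial (0.44 ± 0.31) and secretory scores (0.09 ± 0.34) were not. Dilution stays open. With the GAPDH 3'/5' ratio as a covariate the ductal score was -1.003 ± 0.44 (bound written first, though list medians with this covariate had been computed by then). Adjusting for that ratio thus did not shrink the difference, but the value is only just beyond 2 SE and the ratio differed with batch. RNA quality is therefore not excluded, and the actin 3'/5' ratio was not tried as a covariate. The ductal score itself was -0.22 ± 0.38 without moderate replicate 1.

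Skeletal muscle markers were high in early SS replicate 2. Of 14 measured members 13 were highest in that gland of all 15, for example ACTA1 with a signal of 2224 against at most 175 elsewhere (bound written after), and muscle tissue in the biopsy is a likely source. The exception was MYH7. The list members deviated from the other early glands by 3.28 more than the median of all genes (SD over members 1.70; bound written after), so the rise was not shared by genes at large. Scaling would have removed a common factor on that array beforehand, so this value does not test for one.

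Whether chance can be excluded was asked by splitting the glands of each comparison anew. For SS minus control 1 of 100 splits, the real one, called as many as 562 genes and the highest other 24. Those splits cross the batches. Of the 35 splits that keep each batch's numbers none besides the real one called more than 1. The share of 0.0286 is the smallest that 35 splits allow, and glands change sides only within batch 2. Chance is thus unlikely for this fit but not excluded. For moderate SS minus control it was 1 of 35 (243 against 0) across batches, a share under 0.05 only if batch is ignored. The 5 splits within batches are too few for such a share. For later minus early stages it was 1 of 100 (714 against 629) across batches and 2 of 100 within them, where another split called 914. Both shares are under 0.05, but other groupings of the same glands reached 629 and 914 genes. A count this large is therefore not limited to the real stages, and it does not exclude chance. For early SS minus control the real count was 0 (highest other 4), so all 100 of 100 splits reach it by construction and the test decides nothing.

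Dixon's test marks about 1 in 20 groups by chance, and of 90 tests 6 marked a gland where 4.5 were due. The CHIT1 value of control replicate 1 stood apart from the other controls (Dixon ratio 0.968; signal 21.8 against 3.20 to 3.62). The TNFSF13B value of control replicate 3 did so with a ratio of 0.916 (183 against 77.7 to 83.8). In early SS the MHC class I score of replicate 5 had a ratio of 0.721 (-0.78 against 0.34 to 0.78). Early replicate 2 was marked for its skeletal muscle score (0.766), CHIT1 (0.858; 42.0 against 0.757 to 3.99) and RO60 (0.737; 433 against 908 to 1179). The 714 genes called between later and early stages differ between groups that share a label of disease. The control gland from an SS patient, not in the fit, scored above every non-SS control for 4 of 34 lists, below every one for 15 and between them for 15.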

How the results depend on the processing

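The GAPDH covariate, the removal of the 4 arrays with the highest GAPDH 3'/5' ratio and the stage weights of batch 2 were chosen after the data were seen, and all other settings before. Over 35 settings, 14 of which left out 1 gland, 20375 of 22047 gene values stayed on the main fit's side of the threshold. Of the others 1359 became weaker, 312 stronger and 1 reversed. Of 5406 list values 5016 stayed on their side, 285 became weaker, 84 stronger and 21 reversed. Values called neither in the main fit nor in the setting count among those that stayed. These totals therefore do not tell how often a call held.

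Counts of genes depended on the batch term, on which stages and controls a contrast used and on single glands. Without a batch term SS minus control gave 1672 genes (main 562), moderate 148 (243) and later minus early 191 (714). Batch 2 alone gave 224, 2 (early, main 0) and 921 (moderate, a single gland), and batch 1 alone gave 63 for later minus early. Counting the control gland from an SS patient with the controls gave 1082 for SS. Taking SS as 1 group gave 0 and the main fit with the stage weights of batch 2 gave 20. Like batch 2 alone, both leave the advanced stage out of the contrast, so stages and spread change together there. Only the groups compared gave 1 for early and 672 for moderate, contrasts that rest on early replicates 1 and 2 and on moderate replicate 1 alone, the other SS glands having no control in their batch. Median centring gave 1 for early, no filter 154 for moderate, and array weights 4 for early and 121 for moderate. The GAPDH covariate gave 719 for advanced (1131), and without the 4 arrays later minus early gave 443. Values as deposited gave the main counts.

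Leaving out 1 gland at a time, counts ran from 60 to 721 for SS, 0 to 2 for early, 3 to 383 for moderate, 515 to 1374 for advanced and 203 to 1002 for later minus early. Counts of lists ran from 20 to 23, 17 to 21, 16 to 21, 21 to 26 and 21 to 25. The lowest gene count came without moderate replicate 1 for SS (60), moderate (3) and later minus early (203), and without advanced replicate 2 for advanced (515). As the only moderate gland in the controls' batch, moderate replicate 1 has by design the largest weight of all glands in the SS (0.38) and moderate (0.57) differences. In later minus early its weight is 0.25, no larger than that of either advanced gland. It is, however, the only later-stage gland of batch 2. Without it early replicates 1 and 2 have no later gland in their batch, and the contrast compares the batch 1 glands alone. Leaving out an advanced gland does not have that effect. How much of the fall in count comes from that loss of glands was not tested.

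Lists called depended on the correlation between genes. With an estimated correlation 9 were called for SS (main 23), 0 for early (19), 6 for moderate (19), 9 for advanced (23) and 10 for later minus early (22). fry called 15, 1 and 11 for SS, early and moderate, and without a batch term 9 were called for early.

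Reversed medians without a batch term were, for SS, endothelial -0.31 (main 0.47) and fibroblast -0.22 (0.53), and skeletal muscle 0.0886 (1.09), where the test turned downward. For early SS they were immunoglobulin -0.20, macrophage -0.17, complement -0.17, endothelial -0.14 and fibroblast genes -0.54. For advanced SS skeletal muscle was -0.0830 (1.37) and the gene CXCL8 0.0638 (-1.41). Early myoepithelial markers turned to 0.32 (-0.07) within batch 2, with only the groups compared and without moderate replicate 1, which all give the same contrast. Early immunoglobulin genes turned to -0.25 with the SS patient's control gland. Without early replicate 2 skeletal muscle was -0.00743 for SS and 0.00277 for early. Without moderate replicate 1, SS secretory proteins were 0.11 and myoepithelial markers 0.14, and moderate interferon-stimulated genes 0.10 (test turned), ductal 0.0104, myoepithelial 0.40 and neutrophil markers -0.60. Over single glands left out, the other ends of these ranges were, for SS, secretory proteins -0.36, myoepithelial markers -0.77 and skeletal muscle 1.92. For early SS they were myoepithelial markers -0.29 and skeletal muscle 2.10. For moderate SS, interferon-stimulated genes ran from 0.0719 to 0.45, ductal markers down to -1.08, myoepithelial markers to -0.73 and neutrophil markers up to 0.15.

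No paired analysis was possible because the groups share no pairing and replicate numbers follow accession order only. Only the groups compared was not run for SS, where it equals the main setting, or for advanced SS, where group and batch coincide, and for the same reason no single batch serves for advanced SS minus control. The signal includes background, so changes of weak genes are understated.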

Other observations

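All comparisons here were chosen after the main results were seen; for the lipid-handling genes alone the prediction was written before its own value was computed. Genes with interleukin or interleukin receptor symbols held 13 of 55 measured genes higher in later than in early SS, where 2.06 were due by chance (one-sided Fisher's exact test, adjusted p = 6.33e-06). Among them were IL10RA, IL7R, IL2RG, IL2RB and IL21R. The symbol rule also took in the enzyme IL4I1 and the binding protein IL18BP, which are neither. Chemokine receptors held 6 of 11, namely CXCR4, CCR7, CXCR3, CCR2, CCR1 and CXCR6 (adjusted p = 2.4e-05), while CX3CR1 of that family (-1.19) and IL13RA2 of the interleukin receptors (-1.25) were lower. The GIMAP GTPases of lymphocytes held 5 of 7 (2.4e-05). The MS4A family, which includes CD20, held 4 of 6 (2.31e-04). Of 13 claudins, the proteins of tight junctions, CLDN23 and CLDN8 were lower (0.0399). Between SS and control the GIMAP family again held 5 of 7 (2.4e-05) and chemokine ligands 7 of 24 (1.16e-04). Genes of a family are not independent replicates, and adjustment was over 76 tests.

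Macrophage markers rose with stage by a score of 1.74 ± 0.22, and the question was whether lipid-handling genes rose more. As a mean over the list they rose less: their score minus the macrophage score was -0.94 ± 0.13, -0.83 without a batch term and -0.92 without moderate replicate 1. The members did not move alike. Of 14 measured, 4 were called higher with stage, TREM2 (2.35), LIPA (2.12), NPL (2.08) and FABP5 (1.42). CD36 (-0.50), PLIN2 (-0.21), LGALS3 (-0.14) and CD9 (-0.02) lay below 0, and the others lay between. APOC1, the largest named rise with stage, was not in the list, so the result holds for these members only. T cell markers rose with stage by 1.46 ± 0.20 while type I interferon-stimulated genes stood at -0.20 ± 0.44. The difference was 1.66 ± 0.42 (1.345 ± 0.54 without a batch term and 1.62 ± 0.52 without moderate replicate 1). Interferon-stimulated genes thus rose less with stage than T cell markers, which restates the list results above. Whether they follow lymphocyte content from gland to gland was not tested.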
